A study of Mus musculus with 6 samples.

How the data were processed

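CTCF CUT&RUN libraries of thymic regulatory T cells were grouped by the genotype in the labels, 3 WT and 3 Cgas_KO, and 1 peak list per library was used. Per the submitters' processing notes, Bowtie2 and SEACR 1.3 were used. SEACR calls peaks from blocks of continuous signal. The peak threshold, any control library and the scaling of the signal are not given in the sources used here. The deposited values are signal, the total and the maximum per peak, and are the authors' own values for each peak. They were used to rank peaks and form ratios within a list, and, counted in steps, to describe heights. The heights of peaks in regions of 1 list were also compared between genotypes in steps, where depth is weighed, which assumes that a step means the same in every list. Peaks were called per library, not on pooled libraries.

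The notes list both mm10 and mm39. The lists carry sequence names that belong to mm39, so positions are given in mm39, counted from 1. The gene table at hand is of GRCm38.p6, another build, and no genome sequence was used. Results that need either were therefore not run, namely the promoter share of peaks, genes with a peak at the promoter in 1 genotype only, the share of regions with a CTCF motif, gene lists, and peaks at the Cgas locus and at named T cell genes. The targeted gene could thus not be used to check the genotype labels.

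Peaks on chromosomes 1 to 19, X and Y entered the comparisons. Peaks of all lists were merged into regions at an overlap of 1 bp, and a list had a region when it had a peak in it. Max signal was a whole multiple of 1 step per list within 0.01 step for 100% of peaks under 200 steps, and heights were counted in steps. What a step stands for is not given in the sources used here. Depth per library is unknown, so no counting interval was computed, and the 3 libraries per group limit the precision.

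Values per library were compared with a two-sided exact permutation test over the 20 assignments of 3 against 3, whose smallest p is 0.1. Region counts and Jaccard indices were set beside those of the other splits, 10 in all. Relative signal of regions in all 6 lists was tested with limma 3.58.1 (R 4.3.3) on normal scores of ranks, with Benjamini-Hochberg adjustment at 0.05. It was tested on simulated data, with the same noise SD for all regions of a library, in which 200 of 4896 regions were changed. Of the 4696 unchanged ones 5 were called. Merging was tested on simulated lists of well-separated peaks and returned all planted regions. Neighbouring peaks could not merge in those lists, so this says nothing about crowded peaks. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

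The leading WT-only and Cgas_KO-only regions and the regions named from the relative signal test on ranks followed a rule fixed before the data were examined. The tests of peaks, length, Jaccard index, region counts and relative signal and their alternatives were fixed then too. Other regions, bins and stretches named came from the results. The rule took the 10 WT-only and 10 Cgas_KO-only regions of highest mean percentile of total signal within their lists. Where none passed the relative signal test, it took the 3 smallest p in each direction. The parts of the rule about genes were not run. Alternatives were lists matched to the shortest (27128 peaks), the 50% of each list with the highest total signal, autosomes only, 50% coverage of a region, merging within 500 bp, midpoints of max-signal intervals within 200 bp, 2 of 3 lists, total signal, log2 values, a replicate block and leaving out each library.

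Chosen after the data were examined were the shifted lists, the height ratio, tall peaks and tall regions, the stretches on chromosomes 12 and 1, the bins of 100 kb and 1 Mb, shares per chromosome, the alternatives without those stretches, and leaving out each library with the Jaccard index of both genotypes weighted equally. To leave out the stretches, wider areas of 8 Mb on chromosome 12 and 300 kb on chromosome 1 were removed, with 63 to 141 peaks per list. Tall peaks were first counted at 3, 5 and 10 times the height of peaks in regions of 1 list, and then against the median of the list. The stretches came from a scan of peak density in 1 Mb bins. One explanation for the stretches was first tested on a single 100 kb bin of chromosome 1, where it met the bound set for it, and then, since that bin is 1 of 5, on all of them, where it did not. The bound was set after the values were seen.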

Results

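The deposited data describe where CTCF, a zinc-finger protein that binds DNA and helps to fold chromosomes into loops, was bound in regulatory T cells taken from the mouse thymus. Binding was measured by CUT&RUN, in which an antibody brings a nuclease to the bound protein so that the DNA around it is released and sequenced. There were 3 libraries from wild-type (WT) cells and 3 from cells of Cgas knockout (Cgas_KO) mice, which lack the cytosolic DNA sensor cGAS, and 1 peak list was deposited for each. The stated purpose was to profile CTCF binding in both genotypes. The labels do not say whether the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. All positions are given in mm39, the build whose sequence names the lists carry. No annotation of that build was used here, so regions are named by position and the genes at them were not analysed here.

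The question of how many sites were called in each genotype was answered by the lists on chromosomes 1 to 19, X and Y. The WT lists held 27803 ± 979 peaks (SD, n = 3) and the Cgas_KO lists 29724 ± 1847 (SD, n = 3), a difference within the reach of the replicate spread (two-sided exact permutation test, p = 0.2, Benjamini-Hochberg adjusted 0.263). Peaks covered 104.1 ± 2.99 Mb in WT and 100.2 ± 10.6 Mb in Cgas_KO (SD, n = 3; exact permutation p = 0.8, adjusted 0.884). Cgas_KO replicate 3 had the most peaks, 31707, and the narrowest, with a median width of 2569 bp and 88.1 Mb covered. Without it the Cgas_KO lists covered 2.21 Mb more than the WT lists instead of less. Median widths were 3465 ± 214 bp in WT and 3117 ± 492 bp in Cgas_KO (SD, n = 3; exact permutation p = 0.3, adjusted 0.371). With 3 libraries against 3, no exact permutation test can go below p = 0.1.

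The read depth of the libraries is unknown, because the lists give signal only inside peaks. The max signal of a peak, its height, was a whole multiple of 1 step per list, and heights are given in these steps. The median peak was 11 to 14 steps high. One step was worth 0.199 ± 0.0119 signal units in WT and 0.118 ± 0.00196 in Cgas_KO (SD, n = 3). The signal value of a step thus differed between the genotypes, and whether scaling or depth lies behind this is not given in the sources used here. Signal was therefore tested through ranks and ratios within a list, while heights in steps are given as values. A single region, chromosome 2 from 98491613 to 98498415, held 44.9% ± 0.155 of the total signal in WT and 45.6% ± 0.249 in Cgas_KO (SD, n = 3). It was 888213 to 1289378 steps high. No region was masked, and whether such extreme signal comes from CTCF binding or is an artefact was not tested.

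The 6 lists merged into 94951 regions. Of these, 4896 were called in all 6 lists, against 13 when the lists were shifted against one another by multiples of 2 Mb. Merging chains overlapping peaks, so the peaks of a region need not all overlap one another. The median width of regions in all 6 lists was 7342 bp. When the peaks of each list had to cover 50% of a region, 608 regions were in all 6 lists. At the other end, 66366 regions were called in 1 list only. WT replicates called 7958 regions in all 3 lists and Cgas_KO replicates 6882, and 61.5% of the former were in all 3 Cgas_KO lists while 71.1% of the latter were in all 3 WT lists. At least 1 list of the other genotype held 95.5% of either set.

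**Figure D1:**
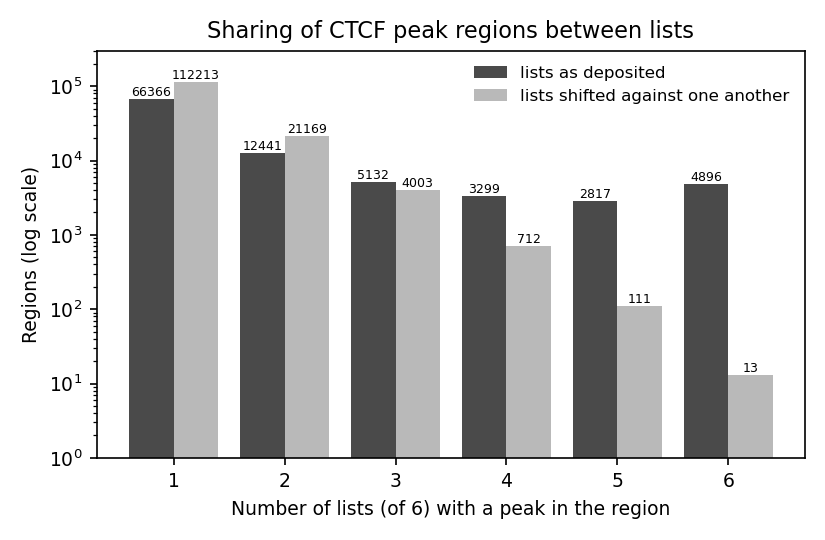
Number of regions (log scale) by the number of lists with a peak in them, for the lists as deposited (dark) and after shifting them against one another (light). Regions in all 6 lists number 4896 as deposited and 13 after shifting.

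The tallest peaks were almost all held in common. This comparison was chosen after the data were examined. Among the 1000 tallest peaks of each list, 713 regions were common to the 3 WT lists, and 700 of them (98.2%) were called in all 3 Cgas_KO lists. In the other direction, 602 regions were common to the 3 Cgas_KO lists and 599 of them (99.5%) were called in all 3 WT lists. The exceptions called in at most 1 list of the other genotype were chromosome 1 from 179302944 to 179306081, chromosome 17 from 33159442 to 33166905 and chromosome 7 from 84398043 to 84403810 for WT. For Cgas_KO they were chromosome 2 from 66017611 to 66020138 and chromosome 4 from 64415741 to 64417126, the last of them called in 0 WT lists at heights of 35 to 47 steps. The 2000 tallest peaks of each list gave 1294 common WT regions, 95.2% of them called in all 3 Cgas_KO lists. They gave 1026 common Cgas_KO regions, 99.5% of them called in all 3 WT lists.

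Averaged over both genotypes, lists of 1 genotype resembled one another slightly more than lists of different genotypes, through the WT lists. The Jaccard index, the length shared by a pair of lists over the length covered by either, averaged 0.173 over the 3 WT pairs, 0.147 over the 3 Cgas_KO pairs and 0.155 over the 9 pairs of different genotype. It was 0.0225 for shifted lists. The Cgas_KO lists were thus less alike on average than a WT and a Cgas_KO list were, through Cgas_KO replicate 3. Its pairs with Cgas_KO replicates 1 and 2 gave 0.144 and 0.142, and its pairs with WT lists 0.146 to 0.148. Cgas_KO replicates 1 and 2 gave 0.157 with each other. The mean of all pairs within a genotype exceeded that between genotypes by 0.00487, and the highest value among the other 9 splits of the 6 libraries was 0.000251. Leaving out 1 library, as planned, gave -0.00197 to 0.0125, with a reversal for each WT library. The weights of the genotypes then change. With both genotypes weighted equally, chosen after the data were examined, it gave 0.00448 to 0.00544.

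Regions called in all 3 lists of 1 genotype and in none of the other were few, 358 for WT and 313 for Cgas_KO. Together these 671 made up 13.1% of the 5132 regions called in exactly 3 lists, where chance gives 10%, and the other 9 splits gave 453 to 551. They were of ordinary strength within their lists, with a median percentile of total signal of 49.3 for the WT-only and 49.5 for the Cgas_KO-only regions, against 83.1 for regions in all 6 lists. No single region can be tested, since Fisher's exact test on 3 against 3 libraries stops at p = 0.1. Which genotype had more such regions depended on the processing. WT-only regions were 53.4% of the total here, 79.1% (468 against 124) when regions were built from the midpoints of max-signal intervals, 64.5% (359 against 198) when peaks had to cover 50% of a region, and 48.1% (2868 against 3098) when 2 of 3 lists sufficed. Both counts also rose by over 1.5 times without any 1 of the 6 libraries. They came to between 658 and 1254 for WT-only and between 506 and 1277 for Cgas_KO-only regions. Leaving out a library asks for 2 lists instead of 3 on its side, or for absence from 2 instead of 3 on the other. A rise is thus built in, and it does not show that the counts hang on single libraries.

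**Figure D2:**
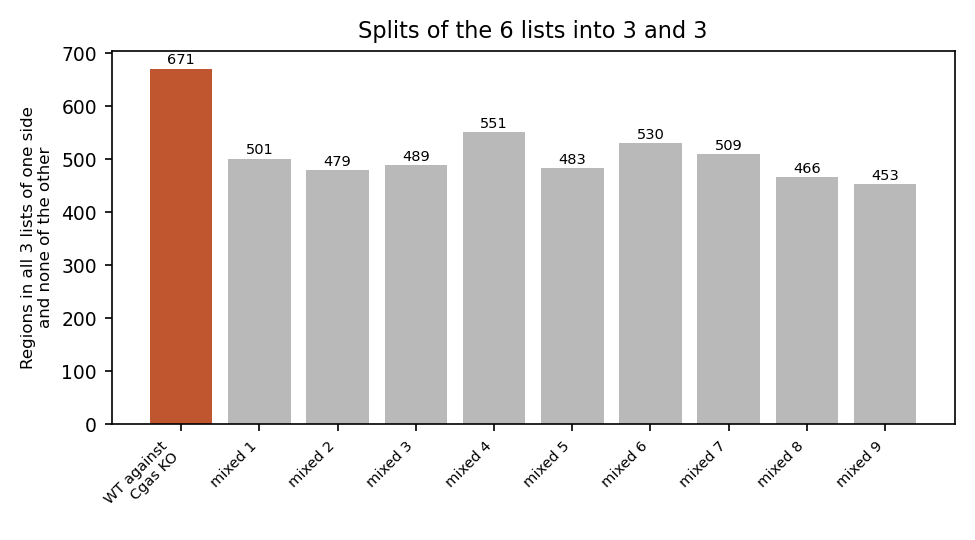
Number of regions called in all 3 lists of one side and in none of the other, for the split by genotype (coloured) and the 9 splits that mix genotypes (grey). The split by genotype gives 671 and the others 453 to 551.

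The 10 leading WT-only regions, by mean percentile of total signal within the 3 lists, clustered on chromosome 12. The first was chromosome 1 from 171398418 to 171409877, at percentile 95.5 ± 1.39 (SD, n = 3). On chromosome 12 there were 6, namely 21628246 to 21639550 (percentile 94.4 ± 1.62), 23273077 to 23282665 (90.2 ± 3.82), 23116383 to 23120904 (86.0 ± 5.01), 20226012 to 20234835 (85.4 ± 10.6), 23249124 to 23272330 (84.7 ± 23.1) and 19236069 to 19243686 (84.2 ± 4.20). The others lay on chromosome 1 from 173775637 to 173784485 (88.3 ± 7.59), chromosome 13 from 113397933 to 113408637 (84.8 ± 8.69) and chromosome 2 from 122141389 to 122147929 (82.1 ± 8.62).

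The 10 leading Cgas_KO-only regions were spread over 8 chromosomes. The first was chromosome 3 from 104676140 to 104682110, at percentile 90.6 ± 2.54 (SD, n = 3). It was followed by chromosome 9 from 66029001 to 66036567 (90.5 ± 5.39), chromosome 19 from 18605366 to 18616680 (87.8 ± 11.3), chromosome 12 from 76822835 to 76827866 (87.5 ± 1.03) and chromosome 11 from 97572391 to 97581587 (86.0 ± 2.71). The remaining ones were chromosome 9 from 88317523 to 88323035 (85.8 ± 3.73), chromosome 11 from 77236202 to 77244435 (84.3 ± 20.6), chromosome 8 from 127391794 to 127396668 (83.6 ± 7.10), chromosome 16 from 94384138 to 94394735 (83.3 ± 7.32) and chromosome 14 from 79747332 to 79757639 (82.5 ± 20.1).

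The stretch of chromosome 12 from 18 to 24 Mb, drawn after these regions and a scan of 1 Mb bins had been seen, held 91 ± 6.08 peaks in WT and 30 ± 5.20 in Cgas_KO (SD, n = 3; exact permutation p = 0.1). Peaks covered 7.50% ± 0.295 of it in WT and 1.62% ± 0.0438 in Cgas_KO (exact permutation p = 0.1, n = 3). The 6 Mb to its left were covered at 3.04% ± 0.172 and 2.97% ± 0.111 (exact permutation p = 0.7, n = 3), while the 6 Mb to its right were covered more in Cgas_KO, 2.55% ± 0.115 against 3.22% ± 0.0853. It held 19 of the 358 WT-only and 0 of the Cgas_KO-only regions. In a 70 kb stretch of chromosome 1 around the first-named WT-only region, peaks covered 76.5% ± 3.80 in WT and 7.90% ± 4.93 in Cgas_KO (exact permutation p = 0.1, n = 3). To the left of it, 70 kb were covered at 18.4% ± 1.12 and 17.8% ± 4.48 (exact permutation p = 0.9, n = 3), and to its right, 70 kb were covered more in Cgas_KO, at 4.65% ± 4.06 against 11.2% ± 2.83 (exact permutation p = 0.1, n = 3). Over the 12 tests of these stretches and their flanks, the lowest Benjamini-Hochberg adjusted p from the exact permutation tests was 0.171. Because both stretches were drawn on this difference, their p-values are not independent evidence of it. Over the genome, 313 of 2587 bins of 1 Mb had peak densities that did not overlap between genotypes, 12.1% where chance gives 10%.

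**Figure D3:**
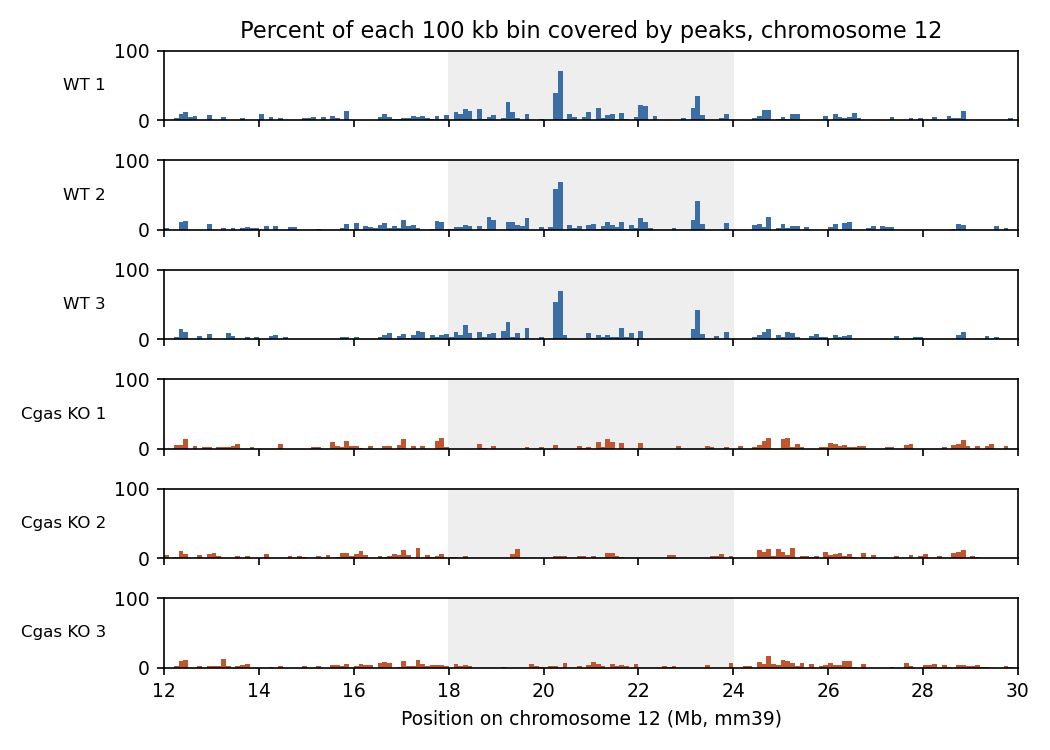
Percent of each 100 kb bin of chromosome 12 covered by peaks, from 12 to 30 Mb, 1 row per list (WT blue, Cgas_KO orange), with 18 to 24 Mb shaded. The shaded stretch is covered at 7.50% on average in WT and 1.62% in Cgas_KO.

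**Figure D4:**
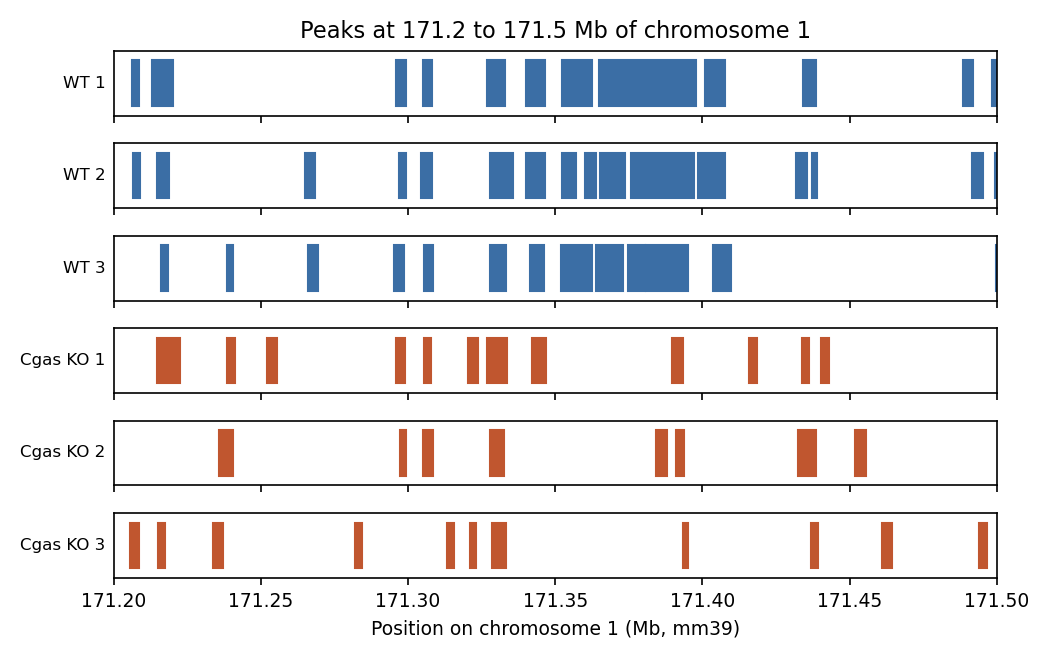
Peaks (blocks) on chromosome 1 around the 70 kb stretch, 1 row per list (WT blue, Cgas_KO orange), against position in Mb. The 70 kb stretch is covered at 76.5% on average in WT and 7.90% in Cgas_KO.

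Whether regions bound in both genotypes differed in relative strength was tested on the 4896 regions called in all 6 lists, as normal scores of the rank of their height within each library. With limma and Benjamini-Hochberg adjustment, 0 regions passed an adjusted p of 0.05, the lowest adjusted p being 0.314. At an unadjusted p under 0.05 there were 461, of which 273 ranked higher and 188 lower in Cgas_KO. The other splits gave 221 to 255. In simulated data the same test recovered 16 of 100 regions changed by 1 on the log2 scale and 85 of 100 changed by 2. Smaller differences would thus mostly be missed. The simulation gave all regions of a library the same noise SD and changed 200 regions at once, which eases the adjustment. Recovery in the real lists may therefore be lower, also for changes of 2. On the log2 scale of height over the median height of these 4896 regions in each library, limma called 1 region, and 897 had an unadjusted p under 0.05. The other splits were not run on this scale.

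That region, chromosome 1 from 171352129 to 171397767, lies in the stretch described above. Its heights were 68, 61 and 73 steps in WT and 14, 20 and 17 in Cgas_KO, a log2 difference of -1.60 (SE 0.23, limma adjusted p = 0.0270), lower in 3 of 3 Cgas_KO libraries. On ranks its limma adjusted p was 0.314. Tall regions were lower in Cgas_KO as a set. Over the height of peaks in regions of 1 list, the median log2 difference was -0.84 in the highest 980 regions and -0.52 in all 4896. These values have another baseline than the -1.60, which is over the median height of the 4896 regions. A drop common to all these regions is thus largely taken out of the -1.60 already. Only the further drop of tall regions, from -0.52 to -0.84, may be part of the difference at this 1 region. Of the regions with the smallest p on ranks, none of which passed, those lower in Cgas_KO were chromosome 5 from 136168930 to 136175022 (43, 33 and 34 steps in WT, 14, 15 and 13 in Cgas_KO), chromosome 11 from 54816223 to 54824763 and chromosome 4 from 106659520 to 106664297. Those higher were chromosome 18 from 4349305 to 4358885, chromosome 4 from 125995124 to 126000277 and chromosome 13 from 24795266 to 24804063 (16, 10 and 15 steps in WT, 25, 28 and 19 in Cgas_KO).

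Peaks stood less high over the rest of their list in Cgas_KO. This measure was likewise chosen after the data were examined. The median height of peaks in regions called in all 6 lists, over that of peaks in regions called in 1 list, was 2.44 ± 0.0315 in WT and 1.76 ± 0.135 in Cgas_KO (SD, n = 3; exact permutation p = 0.1, adjusted 0.15). Peaks at least 5 times the median height of their list numbered 642 ± 52.6 in WT and 284 ± 38.6 in Cgas_KO (SD, n = 3; exact permutation p = 0.1, adjusted 0.15). Adjustment was over the 21 measures per library that were compared, several of them versions of this height pattern. The groups did not overlap in 14 of them, 66.7% where chance gives 10% for a single measure, and the lowest adjusted p was 0.15. The measures are not independent of one another, so 1 pattern can account for many of the 14. The share of 66.7% is thus no separate evidence.

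**Figure D5:**
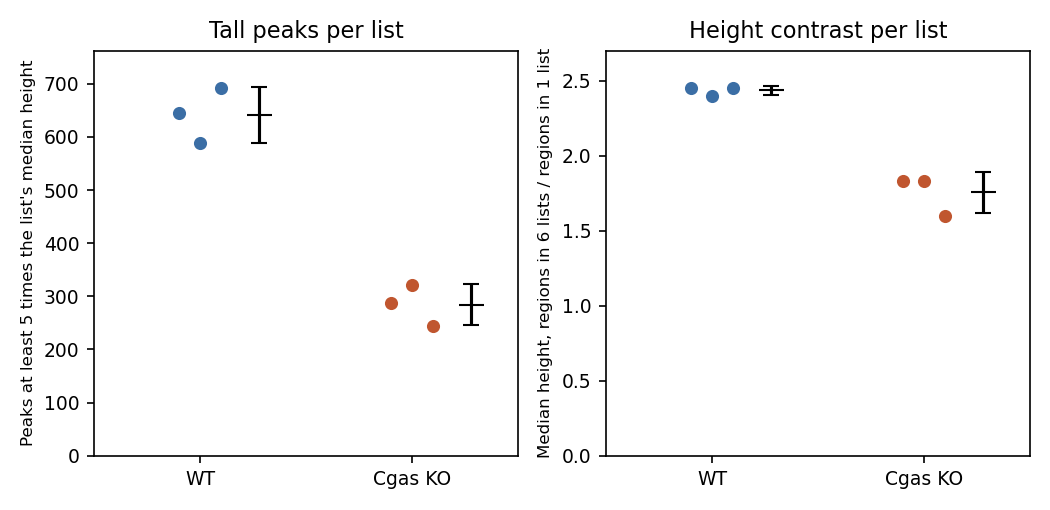
Peaks at least 5 times the median height of their list (left) and the ratio of median heights of regions in all 6 lists to regions in 1 list (right), 1 point per list, with mean and SD beside each group. WT lists average 642 and 2.44, Cgas_KO lists 284 and 1.76.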

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

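Peaks on sequences outside chromosomes 1 to 19, X and Y entered no comparison. All 6 libraries had a peak over the mitochondrial sequence. Unplaced or unlocalised scaffolds held 75 to 88 peaks per library, 79.7 ± 2.08 in WT and 82.3 ± 6.66 in Cgas_KO (SD, n = 3; exact permutation p = 0.6). They were listed here because they hold signal in data not otherwise used, and no explanation was tested.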

How the results depend on the processing

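Alternatives without the areas around the stretches on chromosomes 12 and 1, the equal weighting of genotypes, and all those of the height ratio, tall peaks and tall regions, were chosen after the data were examined. The difference in peaks per library kept its sign in all 8 alternatives, at 929 without Cgas_KO replicate 3 to 2756 without Cgas_KO replicate 2. The height ratio kept its sign in 10 and tall peaks in 13, but none can pass 0.05 with 3 against 3 libraries. These counts include the replicate block, which cannot change a difference between group means here. They also include the height ratio without those areas, whose value did not move, so neither adds support. The difference in length covered was -7.58 to 2.21 Mb when libraries were left out, and reversed to 2.21 Mb without Cgas_KO replicate 3. The Jaccard difference was -0.00197 to 0.0125, and reversed without WT replicate 1 (-0.00116), 2 (-0.00197) or 3 (-0.00130). Leaving out a library turns the weights of the pairs within a genotype from 3 and 3 to 1 and 3, and with both genotypes weighted equally the difference was 0.00448 to 0.00544, so the reversals came from the weights. WT-only regions numbered 211 in the top 50% of each list by total signal, 2868 with 2 of 3 lists and 658 to 1254 with a library left out. Cgas_KO-only regions numbered 159 in that top 50%, 198 at 50% coverage, 124 by midpoints, 3098 with 2 of 3 lists and 506 to 1277 with a library left out. Leaving out a library also eases the requirement from 3 lists to 2 on its side, or from 0 of 3 to 0 of 2 on the other. The higher counts with a library left out are thus built in. Otherwise the cause was not tested.

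Relative signal gave 1 limma call on the log2 scale and 0 in the other 10 alternatives. At an unadjusted p under 0.05, limma gave 487 regions with total signal, 458 without those areas, 357 to 605 with a library left out, and 87 at 50% coverage, where only 608 regions could be tested. With the replicate number as a block there were 0 calls and 422 at an unadjusted p under 0.05, and the difference in peaks was 1920 (exact sign-flip p = 0.5, smallest possible 0.25). Deviations of same-numbered libraries correlated at -0.0129, -0.0169 and -0.0148 across regions, so relative signal gave no sign of a pairing by number. Whether same-numbered libraries shared a day or a batch is not given in the sources used here. The promoter, gene, gene list and CTCF motif results were not run, for want of a reference of the build. Depth, which is unknown, limits how low a peak could be called.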

Other observations

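The shares of peaks per chromosome, compared after the data were examined, differed little. Chromosome X held 3.95% ± 0.0127 of peaks in WT and 3.59% ± 0.0677 in Cgas_KO, chromosome 7 held 6.98% ± 0.0595 and 6.47% ± 0.180, and chromosome 2 held 7.15% ± 0.0680 and 7.61% ± 0.318 (SD, n = 3; exact permutation p = 0.1 each, adjusted 0.525 over 21 chromosomes). Groups did not overlap for 4 of the 21 chromosomes, where chance gives 10%, and other splits reached 6. In bins of 100 kb, 7 differed by at least 20 percentage points in covered length with no overlap, all higher in WT. Of these, 5 lay in the stretches of chromosomes 12 and 1. The others were chromosome 1 from 173700001 to 173800000 (26.9% against 5.69% covered) and chromosome X from 31300001 to 31400000 (54.9% against 28.4%).

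Of the tests below, those of depth, of copy number or strain, of the share of regions lower outside the areas around the stretches and of the limma counts over splits were chosen after the result was seen. The region counts and Jaccard index had been set beside other splits by design, but what those splits would have to show was written down after their values were seen.

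The first pattern is the lower height ratio in Cgas_KO. Height over the list's own baseline was lower in Cgas_KO in 90.9% of the 4896 regions in all 6 lists. The median log2 difference was -0.52, from -0.22 in the lowest 980 by height to -0.84 in the highest 980. The share of 90.9% largely follows from the ratio, which rests on the same regions and baseline, so it is no separate test. Lower enrichment over background in those libraries or lower CTCF occupancy at most sites would each give such values. These cannot be told apart, because library quality was not measured on its own and a difference in it would go together with genotype here. As to lower depth, peaks in regions of 1 list were 12, 12 and 10 steps high in Cgas_KO replicates 1, 2 and 3 and 11, 10 and 11 in WT. They were 0.667 steps higher on average in Cgas_KO (exact permutation p = 0.6, n = 3). The difference was 0.333 without WT replicate 2 or without Cgas_KO replicate 1 or 2, and 1.33 without Cgas_KO replicate 3, whose height ratio was the lowest at 1.60 against 1.83 in the others. The heights of peaks in regions of 1 list are the baseline of the ratio itself, so they are no separate test of depth. In regions of all 6 lists the median peak was 26 ± 1.73 steps high in WT and 20 ± 3.46 in Cgas_KO (SD, n = 3; exact permutation p = 0.1, adjusted 0.15). Lower depth stays open, also because what a step stands for, and so whether it measures depth, is not given in the sources used here. The areas around the stretches on chromosomes 12 and 1 held 8 of the 4896 shared regions, too few to account for the pattern, and of the 4888 outside them 90.9% were lower in Cgas_KO.

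The second pattern is the higher coverage of the stretches on chromosomes 12 and 1 in WT. A candidate explanation is a difference in DNA copy number or strain between the mice, which would raise signal over whole stretches. The chromosome 1 bin, tested first, was covered at 56.5% in WT and 15.5% in Cgas_KO, past the bound of 50% set for that explanation, and all 5 bins together at 47.5% and 4.09%, short of it, but the bins were kept for a difference of at least 20 percentage points, so neither value decides. With no sequenced input DNA used here, this explanation cannot be told apart from a difference in CTCF binding. Of the 10 splits 1, the real one, gave as many differing bins (7, highest other 2), too few splits for a share under 0.05, and outside the areas around the stretches it gave 2 where the highest other also gave 2.

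The third pattern is that the split by genotype stood apart in counts across regions. It gave 671 regions in 1 genotype only against at most 551 in the others, 461 regions at an unadjusted limma p under 0.05 against at most 255, and a Jaccard difference of 0.00487 against at most 0.000251. In each case 1 of the 10 splits, the real one, gave as large a value, and 10 splits are too few for a share under 0.05. The signal value of a step and the height ratio also did not overlap between these groups. A technical difference between the groups would single out the same split, so it cannot be told apart from genotype. No biological explanation was tested.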
